A study of Mus musculus with 2 samples.

How the data were processed

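DNase-seq was measured in 2 kidney samples from female B6CASTF1/J mice aged 25 days, per the labels, which number the samples as biological replicates 1 and 2 of the same tissue. The sample descriptions number the animals differently while both labels carry the same donor identifier, and the replicates were taken as different animals. The samples were treated as 1 group with 2 replicates. The labels name a NovaSeq and a HiSeq instrument for replicate 2 and none for replicate 1, so a difference between the replicates cannot be assigned to animal, library or instrument. The labels give the build mm10. The listing deposited with the files names, per replicate, filtered alignments from which the peaks, per-site false discovery rates and footprints were made, so the authors called each replicate separately. The aligner, the peak caller, the footprint caller and the number of reads were not given in the sources used here.

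Per replicate, 4 tables were used. The authors deposited 2 peak lists, whose signal value (a peak's own value, the authors' and never negative) served to describe, rank and filter peaks. The deposited per-site table gives a false discovery rate, a p-value corrected for multiple testing, for runs of bases, and its values all lie under 0.05. The deposited footprint table gives positions and a value that is 0.01 in each entry, so it ranks nothing and only positions were used. The design had foreseen that the 2 peak lists of a replicate were different kinds of call. Comparison with the per-site table showed 2 stringencies: each peak of the longer list holds a base with a false discovery rate under 0.05, and each peak of the shorter list one under 0.001. The longer lists, whose mean peak length is smaller (170 and 195 bp against 182 and 198 bp), were used in the main analysis, by the rule fixed in the design, and the shorter lists as an alternative.

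Depth per sample was read from the signal values, since no read counts were at hand. The signals of both replicates are whole multiples of a step, 0.00282 in replicate 1 and 0.00609 in replicate 2, for 100% of peaks within a tolerance of 0.05 steps. If a step is the same number of cuts in both, replicate 1 is 2.16 times as deep. What a step stands for is not stated, and absolute depth is unknown, so no interval that needs reads is given. Peaks of a deeper library can reach a threshold at a lower signal, and signal levels across regions were compared as ranks, correlations and ratios relative to the median. Means and SDs of promoter signals were taken from the deposited values, without scaling the replicates to each other. Over all genes with a promoter peak in both, the median log2 ratio of replicate 2 to replicate 1 was -0.45. Each SD of a promoter signal therefore mixes this offset with any spread between animals.

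Genes, transcripts and exons came from the GENCODE release M21 annotation of GRCm38, whose chromosome lengths hold all deposited coordinates, and sequences from the GRCm38.p6 reference, the same build as mm10. Chromosomes 1 to 19, X and Y were used. The reference is C57BL/6J sequence, and alleles of the CAST/EiJ parent were not analysed here.

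Both longer lists were merged where they overlap by at least 1 bp, and merged regions with peaks of both replicates are called shared. Overlap between replicates was set against 100 random placements of each list within the gap-free part of the same chromosome. Locations were assigned by a region's midpoint, in the order promoter (within 500 bp of a protein-coding transcript start), exon, intron and intergenic, with 100 random placements as the chance value. A permutation p from placements cannot fall below 0.0099 (one-sided) or 0.0198 (two-sided). A gene's promoter signal is the highest signal of a peak touching 500 bp on either side of any of its protein-coding transcript starts, and 0 where none is listed. For Xist, which has no protein-coding transcript, and for the Y genes with their X homologs, the starts of all their annotated transcripts were used. A promoter is called CpG-rich if the 500 bp on both sides of the gene's 5' end have a GC content of at least 50% and a ratio of observed to expected CpG of at least 0.6.

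Before the data were examined, 17 lists with 226 genes were fixed, for nephron segments, other kidney cell types, nephric development, posterior Hox genes, other tissues, germ cells and housekeeping, and all 226 genes were found in the annotation. Promoter peaks in both replicates were compared between list genes and all other protein-coding genes with a two-sided Fisher's exact test. Genes of a list are not independent, and no spread between animals enters this test, which describes these 2 kidneys. The number of shared peaks in the gene and 10 kb around it was compared with 10000 random lists of equal size matched on 10 classes of gene length, whose smallest p is 0.0002. Both used Benjamini-Hochberg adjustment over 17 lists. Consensus sequences of 22 motifs, fixed beforehand, were searched on both strands in footprints inside peaks, extended by 5 bp, against equally long windows in the same peaks that touch no footprint, and in 150 bp windows on distal shared regions against windows 1 kb away that touch no peak. Fisher's exact test was used with Benjamini-Hochberg adjustment over 22 motifs. A consensus misses weaker sites and cannot separate members of a factor family.

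Genes named in the text were set by a rule fixed beforehand: the first 4 genes of each list (1 of these genes is not reported here), the 5 list genes with a promoter peak in 1 replicate that have the highest signal, the 10 shared regions with the highest mean rank of signal with the nearest gene, the 10 protein-coding genes with most shared peaks, Xist, and all 22 motifs. The other genes with a peak in the lists for other tissues, immune cells and germ cells, genes on the Y chromosome with their X homologs and gene families by symbol were added after seeing the data.

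The steps were tested on simulated data. All of 9894 planted overlapping intervals were found. Of 100 simulated lists with a promoter peak at all genes, 74% were called, of 100 with a peak at 15% of genes 98%, and of 140 unchanged lists 1.43%. Of 25 simulated lists with peak numbers tripled and then raised further by a constant 88% were called and of 60 unchanged lists 0%, all among 21826 genes. A motif planted in 5% of 20000 windows was found in 5.02%, and none of the 21 other motifs was called. Both sets of simulated windows were random sequence with equal base frequencies. Calls that arise from a difference in GC content were therefore not simulated.

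Alternatives were the shorter lists, the upper 50% of peaks by signal, other overlap rules, promoter windows of 100 and 2000 bp, the starts of all transcripts or the gene's 5' end alone, other windows around genes, footprint extensions of 0 and 10 bp, controls matched on GC content in classes of 5 percentage points, 300 bp windows, false discovery rates of 0.01 and 0.001, and leaving out each replicate. The bins of 20% of peaks by signal, the CpG-poor promoters, the FDR 0.001 lists for the gene lists, the replicate ratio at list promoters and the regions of 1 replicate were added after seeing the data. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and BLAST+ 2.17.0 with a word size of 32. Confidence intervals of shares are 95% Wilson intervals and cover counting error only.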

Results

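DNase-seq maps accessible chromatin by sequencing the ends of DNA fragments that the nuclease DNase I releases from intact nuclei, so that regulatory elements appear as peaks of cutting. It was measured here in kidneys of 25-day-old female mice of the F1 hybrid strain B6CASTF1/J, the offspring of C57BL/6J and CAST/EiJ parents. The samples formed 1 group of 2 biological replicates. The sample descriptions number the animals differently while both labels carry the same donor identifier, so each SD with n = 2 rests on taking the replicates as different animals. Signals were not scaled further between the replicates, so an SD of signals also holds any offset between the libraries, and a small one does not show agreement beyond it. No treatment, age or tissue was compared, so the comparisons were between the replicates, between the peaks and the rest of the genome, and between fixed gene lists or sequence motifs and their backgrounds. All positions refer to the mouse build mm10. The number of reads per library was not given in the sources used here. The peak signal values of each replicate were whole multiples of a replicate-specific step, for 100% of peaks within 0.05 of a step. The step of replicate 2 was 2.16 times that of replicate 1, which corresponds to a deeper replicate 1 if a step stands for the same number of cuts in both.

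The replicates differed strongly in how many accessible regions of the kidney were listed. At a false discovery rate (FDR) of 0.05, 317873 peaks were listed in replicate 1 and 162230 in replicate 2, a ratio of 1.96 (mean 240052 ± 110056 SD, n = 2). They covered 53.6 Mb and 31.3 Mb. The median peak length was 160 bp in replicate 1 and 194 bp in replicate 2, and the mean length over both was 182 bp ± 17.5 (SD, n = 2). Lists at an FDR of 0.001 held 168815 and 108040 peaks, a ratio of 1.56. Single bases with an FDR of at most 0.05 added up to 85.4 Mb in replicate 1 and 53.2 Mb in replicate 2 (mean 69.3 Mb ± 22.8 SD, n = 2). The SD between replicates was large beside these means, so no number of accessible regions in this tissue was fixed more closely than these values.

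The stronger peaks recurred in the other replicate and the weaker peaks of replicate 1 mostly did not. Of the replicate 2 peaks, 73.5% overlapped a replicate 1 peak by at least 1 bp, and 37.8% of the replicate 1 peaks overlapped a replicate 2 peak. Random placement of the peaks on their own chromosomes gave 4.51% and 2.34%, and none of 100 placements reached the observed share (one-sided permutation p = 0.0099 for both, the smallest that 100 placements can give). In the 20% of peaks with the highest signal, 95.7% of replicate 1 peaks and 99.4% of replicate 2 peaks recurred. In the 20% with the lowest signal these shares were 1.09% and 30.8%. When only as many replicate 1 peaks as replicate 2 held were kept, by signal, the shares were 68.6% of replicate 1 and 68.3% of replicate 2.

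**Figure D1:**
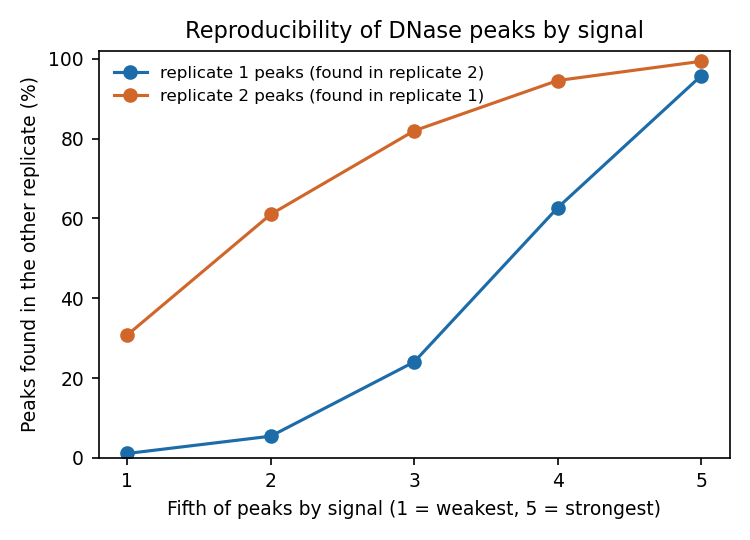
Share of DNase peaks found in the other replicate (at least 1 bp of overlap, in percent) against signal, with the peaks of each replicate divided into 5 bins of 20% from weakest to strongest. Blue circles are replicate 1 peaks and orange circles replicate 2 peaks; the replicate 1 share runs from 1.09% to 95.7% and the replicate 2 share from 30.8% to 99.4%.

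Merging both lists gave 356489 regions, of which 117534 (33.0%) held peaks of both replicates, 196296 a peak of replicate 1 alone and 42659 a peak of replicate 2 alone. The shared regions covered 28.7 Mb with a median length of 220 bp. Across them the signal of the replicates correlated with a Spearman rho of 0.865 and a Pearson r of 0.908 on log2 values, as a description across regions, which are not independent replicates. The median log2 ratio of replicate 2 to replicate 1 was -0.10, and 88.6% of regions lay within 2-fold of the median ratio. At promoters the rho was 0.974 over 20202 regions, and at the other 97332 regions it was 0.817 (Pearson r 0.851).

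Promoters were the most over-represented location. Of the shared regions, 17.2% had their midpoint within 500 bp of the start of a protein-coding transcript, 12.2 times the 1.41% of randomly placed regions. Exons outside promoters held 8.28% (1.78 times the random 4.64%), introns 44.0% (random 42.8%) and intergenic sequence 30.5% (0.597 times the random 51.1%). Each share lay outside the range of 100 random placements (two-sided permutation p = 0.0198, the smallest possible). The excess in introns was small and turned into a deficit with a promoter window of 2000 bp (38.1% against 40.8%) and in the upper 50% of regions by signal (38.6% against 43.0%). With the starts of all annotated transcripts as promoters, introns held 41.8% against 41.9% (permutation p = 0.317). Regions seen in replicate 1 alone lay in promoters in 3.54% and in exons in 11.6% of cases, and those seen in replicate 2 alone in 4.31% and 6.07%.

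The regions with the highest signal in both replicates were mostly promoters. The first was a region at chromosome 17, 6430001 to 6430180, in the promoter of Dynlt1b, which codes for a dynein light chain, with signals of 63.7 in replicate 1 and 49.99 in replicate 2. Promoter regions of Hjurp, which codes for a chaperone of the centromeric histone CENP-A (chromosome 1, 88277521 to 88277760), of Dnpep, Mplkip, Ctdsp2, Bahcc1, Gatad2a and Mxd1 followed, with mean signals between 34.1 for Gatad2a and 43.3 for Hjurp. The remaining regions of these 10 lay close together near the end of chromosome X. A region in an intron at 169997881 to 169998420, 11212 bp from the nearest transcript start (Gm15247), had signals of 127 and 31.8. The promoter region of Gm21887 at 170009921 to 170010160 had signals of 67.8 and 24.3. The replicates differed more at these X regions than at Dynlt1b, but they also differed at Bahcc1 (58.3 and 24.2) and Dnpep (54.2 and 25.9). Whether sequence repeated elsewhere in the genome adds to the signals of the X regions was not tested.

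Chromosome X carried fewer peaks per megabase of gap-free sequence than any autosome in both replicates. It held 70.7 and 26.7 peaks per Mb, against autosomes ranging from 99.7 to 178 in replicate 1 and from 52.9 to 95.2 in replicate 2. Relative to the autosome median this was 0.539 and 0.394 (mean 0.467 ± 0.103 SD, n = 2). The ratio was 0.241 ± 0.00756 (SD, n = 2) in the upper 50% of peaks by signal and 0.313 ± 0.0387 (SD, n = 2) in the FDR 0.001 lists. Chromosome 11 had the highest density in both replicates, 178 and 95.2 peaks per Mb. Xist, the non-coding RNA gene that coats the inactive X chromosome (chromosome X, 103460366 to 103483254), had a signal of 1.63 ± 0.306 (SD, n = 2) within 500 bp of its transcript starts.

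Of 21826 protein-coding genes, 14476 (66.3%) had a promoter peak in both replicates, meaning a peak within 500 bp of any of their protein-coding transcript starts. The share was 95.6% of 9683 genes with a CpG-rich promoter and 43.0% of 12143 genes with a CpG-poor promoter. Among 17 gene lists fixed beforehand, 6 had a higher share than all other protein-coding genes, 5 a lower share and 6 did not pass the test (two-sided Fisher's exact test, Benjamini-Hochberg over the 17 lists).

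Markers of kidney epithelium were widely accessible at their promoters. Of 23 proximal tubule genes, 21 had a promoter peak in both replicates (adjusted p = 0.0245, Fisher's exact test). Examples were Lrp2, which codes for the endocytic receptor megalin (chromosome 2, 69424340 to 69586065), with a promoter signal of 7.41 ± 0.989 (SD, n = 2), Slc34a1, the sodium-phosphate cotransporter of the brush border (chromosome 13, 55398187 to 55415592), with 2.53 ± 0.838, Slc5a2, the glucose transporter SGLT2, with 1.42 ± 0.242, and Cubn, the receptor cubilin, with 1.20 ± 0.759. All 11 genes of collecting duct principal cells had one (adjusted p = 0.0346, Fisher's exact test), among them Scnn1g, a subunit of the epithelial sodium channel, at 4.95 ± 0.293, Hsd11b2 at 1.44 ± 0.341, the vasopressin receptor gene Avpr2 at 0.710 ± 0.349 and the water channel gene Aqp2 (chromosome 15, 99579055 to 99584547) at 0.671 ± 0.380 (SD, n = 2). All 14 podocyte genes did too (adjusted p = 0.00869, Fisher's exact test). Podxl had a signal of 4.83 ± 1.31, Wt1 of 1.46 ± 0.168 and Nphs1, which codes for the slit diaphragm protein nephrin, of 0.648 ± 0.178 (SD, n = 2).

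The other nephron lists did not pass the test. Promoter peaks in both replicates were listed for 9 of 10 genes of the thick ascending limb (adjusted p = 0.219, Fisher's exact test), for 8 of 8 of the distal convoluted tubule (adjusted p = 0.0824) and for 8 of 11 of intercalated cells (adjusted p = 0.808). The distal convoluted tubule list is too short to be called higher, since a peak at all 8 genes gives an unadjusted p of 0.0581 (Fisher's exact test). Umod, which codes for uromodulin, had a promoter signal of 3.005 ± 1.14, and Slc12a1, the sodium-potassium-chloride cotransporter targeted by loop diuretics, of 0.868 ± 0.0302 (SD, n = 2). Cldn16 had 0.266 ± 0.0914, and Cldn19 a signal of 0.525 in replicate 1 and none in replicate 2. The thiazide-sensitive cotransporter gene Slc12a3 (chromosome 8, 94329201 to 94366214) had 1.55 ± 0.509 and 19 shared peaks in or within 10 kb of the gene, Calb1 had 1.30 ± 0.278, Trpm6 0.764 ± 0.408 and Pvalb 0.657 ± 0.199 (SD, n = 2). Among intercalated cell genes, the proton pump subunit gene Atp6v1b1 had 1.56 ± 0.803, Foxi1 0.6003 ± 0.177 and Slc26a4, the chloride-bicarbonate exchanger pendrin, 0.484 ± 0.0654 (SD, n = 2), while Slc4a1 had no promoter peak in either replicate.

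Endothelial and developmental genes were also accessible. All 14 endothelial genes had a promoter peak in both replicates (adjusted p = 0.00869, Fisher's exact test), with signals of 3.66 ± 0.930 for Flt1, 3.03 ± 0.218 for Kdr, 2.24 ± 0.140 for Cdh5 and 1.38 ± 0.508 for Pecam1 (SD, n = 2). Of 15 genes of nephric development, 14 had one (adjusted p = 0.0423, Fisher's exact test), a call that ended with a promoter window of 100 bp (adjusted p = 0.0933), in the upper 50% of peaks by signal (adjusted p = 0.522) and in the FDR 0.001 lists (adjusted p = 0.273). The signals were 8.27 ± 2.61 for the paired-box gene Pax8 and 4.10 ± 1.81 for Pax2, the nephron progenitor gene Six2 had 0.490 ± 0.185, and Gdnf had 0.288 in replicate 1 alone. Stromal and mural genes did not pass the test (11 of 13, adjusted p = 0.274, Fisher's exact test). Pdgfrb had a signal of 1.11 ± 0.344, Col1a1 of 0.804 ± 0.216 and Acta2 of 0.530 ± 0.189 (SD, n = 2), and Ren1, the renin gene, had 0.308 in replicate 1 alone. The 15 housekeeping genes all had a promoter peak (adjusted p = 0.00869, Fisher's exact test), with mean signals from 14.5 for Gapdh over 15.6 for Ppia and 16.99 for Tbp to 18.8 for Actb.

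Markers of other tissues and of immune cells were mostly without a promoter peak in both replicates. The counts were 3 of 15 immune genes (adjusted p = 0.00219), 3 of 15 skeletal muscle genes (adjusted p = 0.00219), 1 of 10 epidermal genes (adjusted p = 0.00219), 4 of 16 hepatocyte genes (adjusted p = 0.00372) and 2 of 10 germ cell genes (adjusted p = 0.00869, all by Fisher's exact test). In replicate 1, whatever replicate 2 held, the counts were higher, with a peak at 8 of 15 skeletal muscle (53.3%), 6 of 15 immune, 6 of 16 hepatocyte, 3 of 10 epidermal and 4 of 10 germ cell genes, beside 73.2% of other genes. The immune genes Ptprc, Csf1r, Spi1 and Cd3e, the liver genes Alb, Cyp7a1 and Cps1, the muscle genes Ckm and Myh4, the keratin genes Krt5, Krt14 and Krt1, and the germ cell genes Prm1 and Zp3 had no promoter peak in either replicate. Of the genes named by the rule fixed beforehand, Fga, the fibrinogen alpha chain, had a signal of 1.82 ± 0.444, and the germ cell gene Dazl one of 5.21 ± 1.12 (SD, n = 2). The other genes of these lists with a peak in both replicates, named after their values were seen, were Mylpf (mean signal 11.9), Ryr1 (1.11) and Actn3 (0.630) of muscle, Krt10 of epidermis (10.1), Apoc3 (2.64), Apob (1.19) and Itih1 (0.430) of liver, Cd14 (0.847), Ikzf1 (0.596) and Lyz2 (0.345) of immune cells and Sycp3 of germ cells (0.989). Myod1, Acta1, Ivl and Ddx4 had a peak in replicate 1 alone, with signals of 0.313, 0.409, 0.274 and 0.288. Neuronal genes did not pass the test (7 of 16, adjusted p = 0.0862, Fisher's exact test): Snap25, Syt1 and Neurod1 had a peak in replicate 1 alone and Rbfox3 had none.

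These calls moved with the promoter definition, the stringency of the peak lists and CpG content. With a promoter window of 100 bp, proximal tubule, collecting duct and nephric development genes were no longer called (adjusted p = 0.0933 for the 3, Fisher's exact test), and with one of 2000 bp collecting duct genes were not (adjusted p = 0.0580). In the FDR 0.001 lists, an alternative added after seeing the data, proximal tubule (adjusted p = 0.0896, Fisher's exact test), endothelial (adjusted p = 0.0501), collecting duct (adjusted p = 0.299) and nephric development genes were not called. In the upper 50% of peaks by signal, podocyte (adjusted p = 0.0891, Fisher's exact test), collecting duct (adjusted p = 0.309) and nephric development genes were not called, and neuronal genes were lower (adjusted p = 0.0194). With the 5' end of the gene as the only start, 73.9% of proximal tubule genes (adjusted p = 0.444, Fisher's exact test) and 71.4% of endothelial genes (adjusted p = 0.769) had a promoter peak, collecting duct (adjusted p = 0.383), podocyte (adjusted p = 0.0571) and germ cell genes (adjusted p = 0.104) were no longer called, and 2 lists stayed higher and 4 lower. Within CpG-poor promoters, a restriction added after seeing the data, 6 lists had a higher share than the 42.9% of the other CpG-poor genes: proximal tubule (90.5%, adjusted p = 0.000131, Fisher's exact test), endothelial (adjusted p = 0.000776), collecting duct (adjusted p = 0.00281), distal convoluted tubule (adjusted p = 0.0114), thick ascending limb and stromal genes (adjusted p = 0.0182 for both). No list was lower there after adjustment, and 1 at an unadjusted p under 0.05 (skeletal muscle, p = 0.0318, Fisher's exact test). The share was 20% for immune genes (adjusted p = 0.139, Fisher's exact test) and 14.3% for skeletal muscle genes (adjusted p = 0.0643), against the 42.9%. It was 10% for epidermal genes (adjusted p = 0.0868, Fisher's exact test), 25% for hepatocyte genes (adjusted p = 0.234) and 0% of 5 germ cell genes (adjusted p = 0.112). All 4 CpG-poor genes of the podocyte and of the housekeeping list (adjusted p = 0.0643 for both, Fisher's exact test) and all 3 of nephric development (adjusted p = 0.112) had a peak, so these gaps were wider than among all promoters and the tests rest on very few genes. CpG-rich promoters were at 10 of 14 podocyte, 12 of 15 nephric development and 11 of 15 housekeeping genes, beside 9683 of 21826 protein-coding genes. The calls of these lists among all promoters can therefore follow in part from CpG content. Among proximal tubule, collecting duct and endothelial genes they were at 2 of 23, 2 of 11 and 3 of 14. In replicate 1 alone, collecting duct (adjusted p = 0.0743, Fisher's exact test), podocyte, endothelial and germ cell (adjusted p = 0.0539 for the 3) and skeletal muscle genes (adjusted p = 0.169) were not called. All collecting duct, podocyte and endothelial genes still had a peak there, beside 73.2% of all protein-coding genes, so their calls ended with the higher background. In replicate 2 alone, 6 lists were higher and 5 lower.

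**Figure D2:**
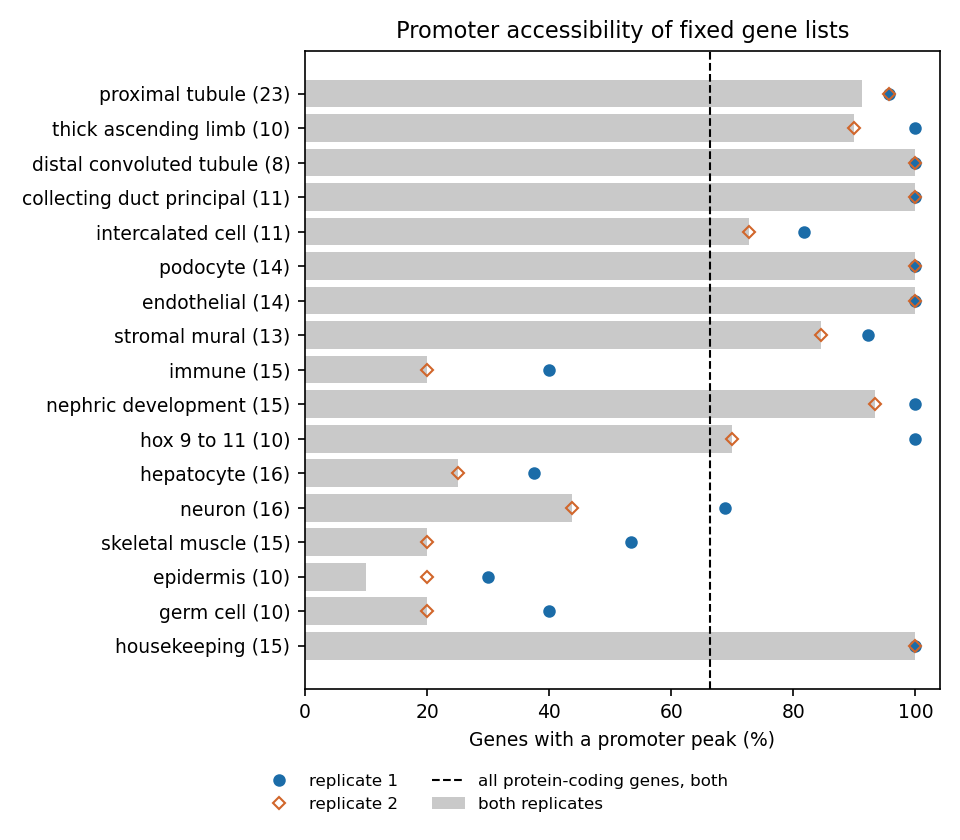
Share of genes (in percent) with a promoter peak for the 17 gene lists, with the number of genes in brackets. Grey bars are peaks in both replicates, blue circles replicate 1, open orange diamonds replicate 2, and the dashed line is the 66.3% of all protein-coding genes with a peak in both; the bars of the lists for other tissues and immune cells end to its left.

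Of the 226 list genes, 28 had a promoter peak in 1 replicate, 26 of them in replicate 1 and 2 in replicate 2. The highest signals among these were in replicate 1 at Hoxa11 (1.29; chromosome 6, 52242106 to 52245810), Hoxd11 (0.709; chromosome 2, 74679557 to 74687016), Hoxc11 (0.646), the organic anion transporter gene Slc22a8 (0.610; chromosome 19, 8591254 to 8611835) and Aqp6 (0.581). The promoter share of the list of Hox genes 9 to 11 was 7 of 10 (adjusted p = 1, Fisher's exact test), with signals of 9.24 ± 3.86 at Hoxa9 and 6.86 ± 0.320 at Hoxa10 (SD, n = 2).

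Within 10 kb, shared peaks were more numerous around proximal tubule, endothelial and posterior Hox genes than around matched genes. The median number of shared peaks in the gene and 10 kb on both sides was 8 for proximal tubule genes, against 4 for 10000 random lists matched on gene length (adjusted p = 0.0408, two-sided permutation test, Benjamini-Hochberg over 17 lists). It was 10.5 against 5 for endothelial genes (adjusted p = 0.0391, permutation test), with 29 at Flt1 and 18 at Pecam1. It was 14 against 2 for Hox genes (adjusted p = 0.0034, permutation test), with 22 at Hoxa9 and 17 at Hoxa10. Neighbouring Hox genes share these windows, so their counts are not independent and this p is too small. Medians lay below those of matched lists for epidermal, skeletal muscle, immune, hepatocyte, neuronal and germ cell genes without passing the test; the lowest unadjusted p was 0.107 (epidermal genes, permutation test). Medians for the other lists ran from 0.5 for epidermal genes (matched 3) and 1 for skeletal muscle genes (matched 3) to 9 for distal convoluted tubule (matched 6) and 9.5 for podocyte genes (matched 5, adjusted p = 0.0816, permutation test). They were 2 for immune and hepatocyte genes, 2.5 for germ cell, 3.5 for neuronal, 4 for collecting duct, stromal and nephric development genes, 5 for intercalated cell, 5.5 for thick ascending limb and 6 for housekeeping genes. In the gene body alone none of the 3 lists was called (adjusted p = 0.82, 0.386 and 0.177, permutation test), endothelial genes were not called in either replicate alone (adjusted p = 0.0918 for replicate 2 and 0.197 for replicate 1), and within 50 kb proximal tubule (adjusted p = 0.0997) and endothelial genes (adjusted p = 0.192) were not called while Hox (adjusted p = 0.0034) and housekeeping genes (adjusted p = 0.0221) had more. Without peaks within 2000 bp of a transcript start, proximal tubule and endothelial genes stayed called (adjusted p = 0.0034 for both, permutation test) and the Hox median was 1 (adjusted p = 1).

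The genes with most shared peaks in and within 10 kb of them had long annotated spans. Gm20388 held 601 peaks over an annotated span of 4435 kb and the growth factor receptor gene Fgfr2 held 248 over an annotated span of 2961 kb. The span of Gm20388 includes Gse1 and that of Fgfr2 includes a gene of the intercalated cell list. Both counts therefore take in peaks at other genes. Tns1, which codes for the focal adhesion protein tensin 1, held 110 peaks over 214 kb (chromosome 1, 73910231 to 74124449). Pde4d held 91, Gse1 86, Syn3 74, Nav2 and Lrmda 73 each, Camta1 72 and Prkce 71.

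Footprints are short stretches protected from cutting inside accessible regions, where a bound protein can shield the DNA. The deposited footprints numbered 544913 in replicate 1 and 346909 in replicate 2 (mean 445911 ± 140010 SD, n = 2), with mean lengths of 12.6 and 12.7 bp. Inside peaks of the same replicate lay 84.5% and 87.1% of them. Of the footprints inside peaks, 32.2% of replicate 1 touched a footprint of replicate 2, against 21.3% after random placement within the same peaks. In the other direction it was 52.7% against 33.7% (one-sided permutation p = 0.0099 for both, the smallest possible). Where at least 50% of both footprints had to overlap, the shares were 22.8% (random 7.35%) and 35.9% (random 11.2%). Among footprints in shared regions alone, with at least 1 bp of overlap, they were 52.9% (random 35.1%) and 59.6% (random 38.2%).

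The motif of CTCF, a zinc finger protein at insulators and loop anchors, was strongly enriched in footprints. It occurred in 0.897% of replicate 1 footprints and 1.68% of replicate 2 footprints extended by 5 bp, 103 and 126 times its share in equally long windows of the same peaks outside footprints. The size of this ratio depended on the extension, at 938 and 582 times without it and 47.8 and 57.01 times with 10 bp. Of 22 motifs, 12 were more frequent in footprints in both replicates, 4 less frequent, and 6 were not called in both (two-sided Fisher's exact test, Benjamini-Hochberg over 22 motifs, adjusted p below 0.05 required in each replicate). Motifs of factors of kidney epithelium were among the more frequent ones: HNF1 at 6.75 and 13 times the control share (adjusted p = 4.39e-05 and 1.24e-16, Fisher's exact test), the HNF4 direct repeat at 3.48 and 5.48 times, and the estrogen-related receptor motif at 1.65 and 1.87 times. The HNF1 ratios rest on 27 and 78 footprints against 4 and 6 control windows, and were 3.50 and 13.9 with an extension by 10 bp. The direct repeat bound by PPAR and RXR was found in 0.00565% and 0.00807% of footprints, and in 0.000236% of control windows of replicate 1 and in none of replicate 2. Other motifs were enriched with ratios of 12.3 and 14.4 for SP and KLF, 2.39 and 2.23 for ETS, 1.43 and 1.34 for NFY, 1.66 and 1.37 for TFAP2 and 5.29 and 12.2 for CEBP. NRF1 was found in 0.0561% and 0.0989% of footprints and 0.00212% and 0.000351% of control windows. REST was found in 0.00212% and 0.00281% of footprints and in no control window (adjusted p = 0.00452 and 0.00955, Fisher's exact test), though its 21 bp consensus fits in the longer windows alone.

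The motifs less frequent in footprints than in control windows were FOX (0.224 and 0.345 times), GATA (0.408 and 0.512), GRHL (0.43 and 0.574) and the POU octamer (0.462 and 0.669). The collecting duct list holds a GATA gene and the intercalated cell list the FOX gene Foxi1, so motifs of kidney epithelial factors went both ways. AP-1 (0.969 and 1.12), TEAD (0.869 and 1.21), the glucocorticoid response element (0.684 and 3.50), the myogenic E-box (1.34 and 1.09), MEF2 (0.424 and 1.05) and ONECUT (0.477 and 0.912) were not called in both replicates. Footprints had a mean GC content of 59.5% and 56.5% in the 2 replicates and control windows one of 54.1% and 52.7%. With controls matched on GC content, AP-1 and TEAD were more frequent in footprints (mean ratios 1.22 and 1.37), the SP and KLF ratios were 6.16 and 8.07, TFAP2 and the octamer were no longer called in both replicates (mean ratios 1.16 and 0.803), and neither was REST (5 footprints and no control window in replicate 1, adjusted p = 0.0724, Fisher's exact test). Without the extension by 5 bp the mean TEAD ratio was 0.539, the SP and KLF ratios were 32.3 and 40.9, those of HNF4 5.22 and 11.5, those of FOX 0.067 and 0.122, and TFAP2 was not called in replicate 2 (ratio 1.22, adjusted p = 0.365, Fisher's exact test). With an extension by 10 bp the SP and KLF ratios were 7.33 and 9.28, those of HNF4 2.61 and 4.32 and those of FOX 0.440 and 0.569. At this extension neither TFAP2 (ratio 1.21, adjusted p = 0.0572, Fisher's exact test) nor the octamer (ratio 0.926, adjusted p = 0.358) was called in replicate 2. With controls matched on GC content the HNF4 ratios were 5.40 and 6.52 and the FOX ratios 0.369 and 0.440.

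**Figure D3:**
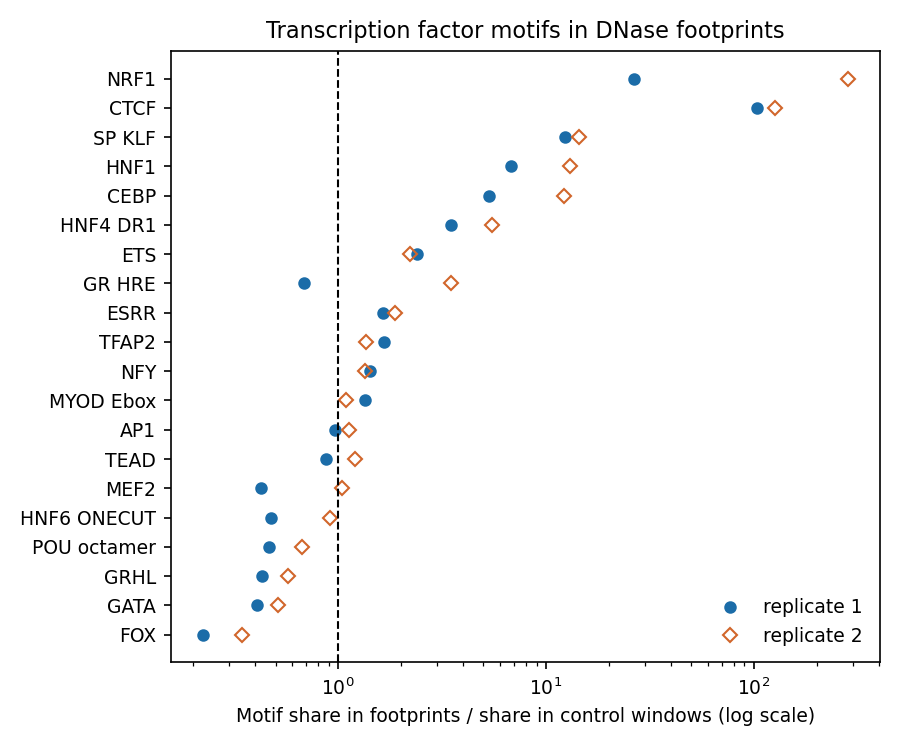
Share of footprints with a motif divided by its share in control windows of the same peaks (log axis, no unit) for the 20 motifs with a ratio in both replicates. Filled blue circles are replicate 1 and open orange diamonds replicate 2; CTCF lies at 103 and 126, HNF4 DR1 at 3.48 and 5.48, and FOX at 0.224 and 0.345, with the dashed line at equal shares, and the NRF1 ratio of replicate 2 rests on 1 control window.

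Distal shared regions, over 2000 bp from any annotated transcript start, carried many of the same motifs. In 72267 windows of 150 bp on their midpoints, CTCF occurred in 5.78%, against 0.0484% of windows 1 kb away that touched no peak (119 times). Of the 22 motifs, 18 were more frequent in the regions, 2 less frequent and 2 were not called (two-sided Fisher's exact test, Benjamini-Hochberg). HNF1 was 14.6 times as frequent (0.101%, adjusted p = 3.24e-16, Fisher's exact test), the HNF4 repeat 7.14 times (1.29%), the PPAR and RXR repeat 6.67 times and the glucocorticoid response element 6.13 times (0.0678%, adjusted p = 4.95e-08, Fisher's exact test). AP-1 occurred in 4.70% of the windows (1.84 times), TEAD in 1.44% (1.97 times) and the myogenic E-box in 3.48% (2.89 times). The ratios were 4.33 for NRF1, 4.27 for CEBP, 3.48 for ETS, 3.26 for SP and KLF, 3.10 for TFAP2, 1.72 for MEF2, 1.35 for the estrogen-related receptors, 1.26 for GRHL and 1.18 for FOX. REST occurred in 8 windows and no control window (adjusted p = 0.00859, Fisher's exact test). GATA (0.672 times) and ONECUT (0.376 times) were less frequent, and NFY (1.04 times, adjusted p = 0.0735) and the POU octamer (0.921 times, adjusted p = 0.172, Fisher's exact test) were not called. The windows in regions had a mean GC content of 52.2% against 44.8% in controls. With controls matched on GC content, the calls for the estrogen-related receptors (ratio 1.14), NRF1 (ratio 1.78) and REST (in no window of either kind) ended and the octamer was more frequent in the regions (ratio 1.90). The ratios of other called motifs fell to 1.29 for SP and KLF, 1.83 for TFAP2, 1.84 for the myogenic E-box and 2.09 for ETS and rose to 1.78 for FOX, 4.32 for MEF2, 6.25 for CEBP and 14 for the PPAR and RXR repeat, and HNF1 was left in no control window. For the PPAR and RXR repeat the matched ratio rests on 14 windows against 1 control window and the unmatched one on 20 against 3. For CEBP the counts were 25 against 4 and 47 against 11, so the sizes of both rises are uncertain.

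Distal regions seen in 1 replicate differed in motif content, in a comparison added after seeing the data. In the 33543 distal regions of replicate 2 alone, CTCF occurred in 2.78% (95% Wilson interval 2.61% to 2.96%), HNF1 in 0.203% (0.16% to 0.257%) and HNF4 in 1.37% (1.25% to 1.502%). In the 155582 distal regions of replicate 1 alone, CTCF occurred in 0.179% (0.159% to 0.202%), HNF4 in 0.215% (0.193% to 0.24%) and HNF1 in 0.00129%, which rests on 2 regions. All 74517 shared distal regions held CTCF in 5.73%, HNF1 in 0.103% and HNF4 in 1.29%. Shared distal regions of the same replicate 2 signal as the regions of replicate 2 alone held CTCF in 2.01%, HNF1 in 0.0343% and HNF4 in 0.798%, so at equal signal the regions of replicate 2 alone had the higher shares of these 3 motifs. The TEAD share was also higher, at 1.60% (1.47% to 1.74%) against 1.28%, and the AP-1 share was lower, at 3.91% (3.71% to 4.12%) against 4.72%. At the replicate 1 signal of the regions of replicate 1 alone, shared ones held CTCF in 3.49%, HNF1 in 0.0735% and HNF4 in 0.964%, all above those of replicate 1 alone. So were TEAD (1.41% against 0.654%) and AP-1 (4.03% against 3.29%). These intervals cover counting error only, not the spread between animals. The mean GC content of all regions was 46.7% for replicate 2 alone, 53.5% for replicate 1 alone and 55.0% for shared regions.

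**Figure D4:**
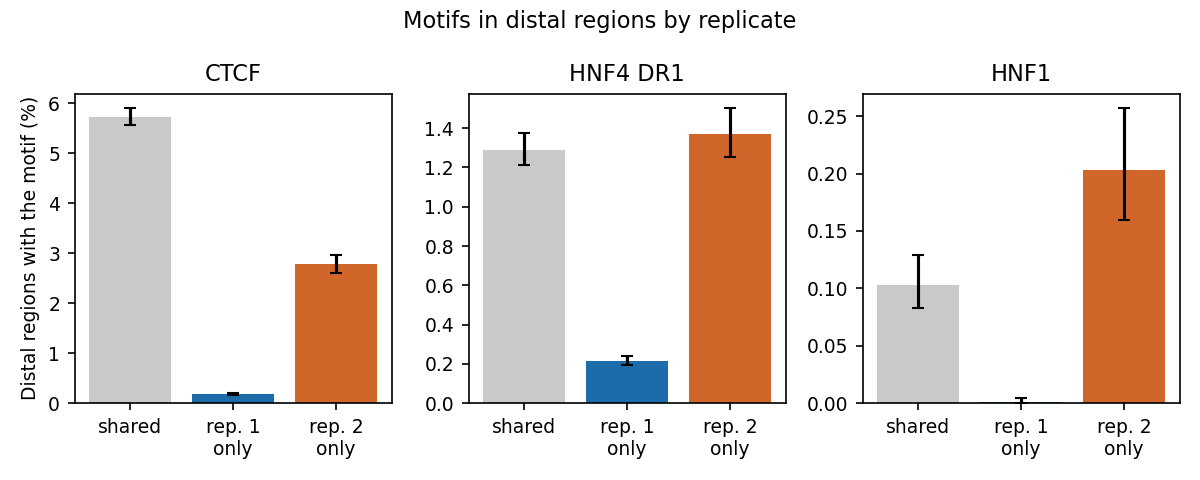
Share of distal regions (in percent) with the CTCF, HNF4 DR1 or HNF1 motif in 150 bp windows, for shared regions (grey), regions of replicate 1 alone (blue) and of replicate 2 alone (orange), with 95% Wilson intervals as error bars and a separate vertical scale per motif. CTCF stands at 5.73%, 0.179% and 2.78% and HNF4 DR1 at 1.29%, 0.215% and 1.37%.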

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

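Of the tests in this part, that of the CTCF motif in regions of replicate 1 was chosen only after the result it measures was seen, and both patterns were noticed in the data.

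Peaks were listed on the Y chromosome although both mice are female, 148 in replicate 1 and 47 in replicate 2. They were flagged because no result above had examined them by themselves and both counts lie above the 3 that a count of 0 allows, which says nothing about their source. Protein-coding Y genes and their peaks were part of the background of all protein-coding genes in the list and family tests. They make up 0.0466% and 0.029% of the peaks, and 31 in each replicate overlap a peak of the other. Male tissue is argued against, since 0 of 6 Y genes (Kdm5d, Uty, Ddx3y, Eif2s3y, Usp9y and Zfy1) had a promoter peak in either replicate. Their X homologs had mean signals from 5.28 for Eif2s3x to 37.1 for Kdm6a. Male kidneys were not examined, so how many of the 6 would carry a peak there is unknown. An amount of male DNA too small to give peaks stays open. A candidate explanation is reads from sequence that the Y chromosome shares with other chromosomes: 72.8% of the 195 Y peaks matched another chromosome with at least 90% identity over at least 80% of their length, against 37.5% of 200 random Y windows (p = 1.75e-12, Fisher's exact test). The 195 are the peaks of both replicates counted separately, including the 31 of each that overlap, so they are not independent and this p is too small. No biological explanation was tested.

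Replicate 1 listed 1.96 times as many peaks as replicate 2. One explanation is that replicate 1, the deeper library if a signal step is the same number of cuts in both, shows weaker elements of the same kind as the shared ones. Against it, distal regions seen in replicate 1 alone carried the CTCF motif in 0.179% (95% interval 0.159% to 0.202%), which is 5.14% of its share in shared distal regions of the same replicate 1 signal (3.49%). The shared regions also had to be listed in replicate 2, so part of this gap can come from their selection. Regions of replicate 2 alone, set apart in the same way, held CTCF in 2.78% against 2.01% at equal replicate 2 signal. The 0.179% covers all 155582 regions, of which 148232 lay in signal classes with enough shared regions to compare. The share for HNF4 was 0.215% against 0.964%, and for AP-1 3.29% against 4.03%, so weaker elements of other kinds, with little CTCF, stay open. The regions of replicate 1 alone lay in exons in 11.6% (95% interval 11.5% to 11.7%). Random windows with their GC content did so in 9.25%, 79.8% of that share and below the 90% set beforehand, and random windows without that match in 4.59%. These windows were placed on all gap-free sequence, while peaks can only be listed where reads can be assigned. The test therefore cannot decide whether the GC content of background cutting accounts for the whole exon share. Differences between the libraries, nuclei or sequencing runs stay open and cannot be separated with 1 library per replicate, and no biological explanation was tested because the design has a single group.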

How the results depend on the processing

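The CpG-poor promoters and the FDR 0.001 lists for gene lists were alternatives chosen after seeing the data. No paired analysis was possible because the samples form 1 group. Over all alternatives, 78 values of main results stayed on their side of the test or within the limit set for them, 16 moved and 3 changed direction; of values of single lists and motifs, 302 stayed, 44 were no longer called, 14 became called and 4 changed direction. Overlaps of peaks and of footprints exceeded chance under each alternative run with random placements. The bins of peaks by signal had no chance value of their own. The 1.09% of the weakest replicate 1 bin lies below the 2.34% for random placement of all replicate 1 peaks.

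The mean number of peaks was 138428 in the FDR 0.001 lists and 120788 in the upper 50% by signal, where the mean length was 209.5 bp; both lists are shorter by construction. The Spearman correlation of signal was 0.974 at promoters and 0.817 elsewhere. The X ratio was 0.241 in the upper 50% and 0.313 at FDR 0.001, and the length with a false discovery rate of at most 0.001 was 42.5 Mb. The intron share fell below chance with a 2000 bp window (38.1%) and in the upper 50% (38.6%), and lay within the range of chance with all transcript starts (41.8%, permutation p = 0.317); promoters take up a larger share in each case.

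Lists with a higher promoter share numbered 3 with a 100 bp window, 2 with the 5' end alone, 3 in the upper 50% and 2 at FDR 0.001, and from 3 to 6 without a replicate (3 without replicate 2). Lists with a lower share numbered 0 among CpG-poor promoters, and from 3 to 5 without a replicate (3 without replicate 2). Lists with more peaks around the gene numbered 0 in the gene body alone and 2 to 3 without a replicate. Nephric development genes, at the middle of the random lists in shared peaks, had a median of 18 peaks without replicate 2 (adjusted p = 0.0487, permutation test, matched 8).

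In footprints the TEAD ratio was 0.539 without extension. In distal regions the octamer ratio was 1.90 with controls matched on GC content and the NFY ratio 0.963 in 300 bp windows, where 4 motifs were less frequent. Except where the construction of an alternative is named, the cause was not tested. Ranking footprints by their score was not run, since its value is constant.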

Other observations

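All tests in this part were chosen after the result was seen or added after the data were examined.

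Large gene families separated clearly by promoter accessibility. Of 20 families taken by symbol, 6 had a promoter peak in both replicates more often and 8 less often than other protein-coding genes (two-sided Fisher's exact test, Benjamini-Hochberg over 20 families). Olfactory receptors had one at 13 of 1133 genes and vomeronasal receptors at 2 of 330 (adjusted p = 1.61e-152, Fisher's exact test), against 8 of 53 keratins and 6 of 42 beta-defensins. Solute carriers, which move ions and metabolites across membranes, had one at 300 of 371 genes (80.9%, adjusted p = 1.83e-09, Fisher's exact test). All 46 genes with the symbol prefix Nduf, called mitochondrial complex I genes here, had one. So did 90 of 98 genes with the prefix Rpl or Rps, called ribosomal protein genes here. Both prefixes can also take in genes whose products are not parts of complex I or the ribosome. The counts were 47 of 50 for proteasome, 22 of 23 for vacuolar proton pump and 345 of 394 for zinc finger genes. Cytochromes P450 (39 of 100), interleukins and their receptors (33 of 82), claudins (15 of 33) and UDP-glucuronosyltransferases (9 of 22) had one less often, with adjusted p values of 6.01e-08, 3.2e-06, 0.0239 and 0.0303 by Fisher's exact test. Hox (28 of 39), forkhead (25 of 44), organic ion transporter (15 of 25), aquaporin (7 of 11), potassium channel (69 of 94) and collagen genes (31 of 45) did not pass the test. CpG content was not held fixed in these tests. CpG-rich promoters, which 9683 of 21826 protein-coding genes have, were at 9 of 100 cytochromes P450, 10 of 82 interleukins and receptors, 4 of 33 claudins and 1 of 22 UDP-glucuronosyltransferases. The promoter shares of these 4 families lie near the 43.0% of all CpG-poor genes, so their deficits can follow from CpG content, while olfactory receptors, keratins and beta-defensins, with no CpG-rich promoter, lie below it. CpG-rich promoters were at 36 of 46 complex I, 71 of 98 ribosomal protein and 35 of 50 proteasome genes, 167 of 371 solute carriers, 188 of 394 zinc finger, 11 of 23 proton pump and 31 of 44 forkhead genes.

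The ratio of replicate 2 to replicate 1 signal at list promoters had a median log2 value of -0.45 over all genes with a peak in both. The proximal tubule median was -0.15, at percentile 94.95 of 10000 random lists of the same size matched on signal, whose median was -0.32 (95% range -0.51 to -0.12) and which it did not leave. The Hox median was -0.69, at percentile 1.76 of its matched lists (median -0.40, 95% range -0.67 to -0.07). Medians for the other lists were -0.13 for neuronal, -0.18 for podocyte, -0.29 for collecting duct, -0.44 for distal convoluted tubule and nephric development, -0.47 for endothelial, -0.50 for intercalated cell, -0.51 for thick ascending limb, -0.56 for stromal and -0.60 for housekeeping genes. These are 2 libraries, and the differences were not tested between animals.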
